A study of Mus musculus with 12 samples.

How the data were processed

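Gene expression was measured in cultured mouse cardiac fibroblasts on 12 arrays, 3 for each of 4 groups: untreated, PDGF-AB at 50 ng/ml, AG1296 at 1 uM and AG1296 at 10 uM. Per the labels, total RNA was isolated with a Qiagen micro kit, RNA with an integrity number above 8.0 was accepted, and 100 ng was labelled with biotin by the Affymetrix WT kit and hybridised to 1-colour arrays. The deposited values are log2 expression per probe set. Per the labels the authors used RMA, which subtracts background, normalizes across arrays and summarises the probes of a set, and limma, with no versions and no settings given. The log base is not written in the table and was read from the range of the values. The values were used as deposited, with no further normalization.

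The table held 28853 probe sets. Of these, 5443 (18.9%) had no gene symbol in the platform table and 1621 (5.62%) had several; both kinds were left out of the gene-level tests. The other 21789 probe sets (75.5%) had exactly 1 symbol, and 21698 of them matched a current gene record by gene ID, which changed 0 symbols. For the 999 genes with more than 1 such probe set, the one with the highest mean over all 12 arrays was kept, which gave 19938 genes. No filter on dim probe sets was applied.

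Differential expression was tested with limma 3.58.1 in R 4.3.3. All 12 arrays entered 1 linear fit with a mean per group, followed by empirical Bayes moderation of the variance (prior degrees of freedom 5.35, residual degrees of freedom 8, median residual SD 0.15 on the log2 scale). The comparisons were PDGF-AB, AG1296 10 uM and AG1296 1 uM against untreated, AG1296 10 uM against AG1296 1 uM, and PDGF-AB against AG1296 10 uM, with an F test over the 4 groups. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are differences of group means on the log2 scale with their standard error (SE) from the fit, n = 3 arrays per group. The number of arrays limits the precision. The p-values measure the spread between arrays, since the labels do not say whether arrays came from separate cultures or animals.

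The groups, the comparisons, the tests, 35 lists of genes and the rule for naming genes were fixed before the data were examined. The lists covered the PDGF receptors and ligands, other kinases that AG1296 is known to bind, ERK pathway feedback, immediate early genes, mitosis, DNA replication, sterol and fatty acid synthesis, interstitial matrix, basement membrane, matrix proteases, TGF-beta and YAP/SRF targets, myofibroblast genes, fibroblast identity, Wnt, ATF4, NRF2, aryl hydrocarbon receptor, p53, FOXO, interferon, complement, chemokines, glycolysis, oxidative phosphorylation, ribosomal proteins, adipogenic and osteo-chondrogenic genes, and markers of endothelium, pericytes, cardiomyocytes, leukocytes, epicardium, Schwann cells and erythroid cells. They held 681 genes, of which 630 were measured, 19 lay on probe sets with several symbols and 32 had no probe set under their symbol. The erythroid list had fewer than 3 measured members and was not analysed here. The other 34 lists were tested with camera of limma at its preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over all 170 tests of lists and comparisons. Beside it stand camera with an estimated correlation, and the members' own calls over all genes and adjusted over the list alone. The fry test was also run.

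Against untreated, the rule named the 10 largest rises and the 10 largest falls among called genes whose 3 treated arrays all lay beyond the 3 untreated ones, and 5 each way between treatments. It added up to 4 members of each list and the genes Pdgfra, Pdgfrb, Kit, Pdgfa, Pdgfb, Ly6a and Pecam1. Predicted genes, olfactory and vomeronasal genes, microRNAs, and small nuclear, nucleolar and ribosomal RNAs were counted but not named; Y RNAs were not among these. Genes and gene classes chosen after their values were seen are said to be so where they appear. Tnc, and Nid1 between PDGF-AB and AG1296 10 uM, were named as single exceptions in a list after their values were seen and were not refitted under the alternatives. Similarity of the responses was compared with 100 simulated sets of unchanged groups that shared the same untreated arrays, since 3 controls cannot be divided.

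The test was tried on simulated data with the spread of these arrays, for AG1296 10 uM against untreated over 19938 genes, in 10 data sets with 200 changed genes each. It recovered 48.0% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1, and 4.68% of its calls were false. A comparison simulated without change gave 0.1 calls on average. A list of 28 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 10 of 10 data sets, and an unshifted list in 0. Genes were simulated as independent, so this does not show how often lists of correlated genes pass falsely.

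The alternatives tried were an adjusted p under 0.01, a 2-fold minimum, a filter for genes above the array median in at least 3 arrays, the mean of a gene's probe sets, all probe sets, quantile normalization, median centring of each array, an intensity trend with robust moderation, estimated array weights, only the 6 arrays compared, the replicate number as a fixed or random block, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.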

Results

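Gene expression was measured on 12 arrays in cardiac colony-forming-unit fibroblasts (cCFU-F), cells sorted from mouse hearts as SCA1 and PDGFRα positive and CD31 negative and then grown in culture. The gate selects interstitial fibroblasts and leaves out endothelial cells. The mice were C57BL/6 males aged 12 weeks. Cells were left untreated, given the ligand PDGF-AB at 50 ng/ml, which activates the PDGF receptors, or given AG1296 at 1 uM or 10 uM. AG1296 is a tyrosine kinase inhibitor of the PDGF receptors that also binds c-Kit and FGF receptors. Each group had 3 arrays. The length of treatment and the vehicle are not given in the sources used here. Any effect of a vehicle therefore cannot be told apart from that of the treatments. Values were log2 expression, with array medians from 4.02 to 4.13. Across genes, which are not independent replicates, arrays of the same group correlated at r of 0.992 to 0.996. PDGF-AB replicate 1 stood farthest from the other groups, with a mean r of 0.990 to their arrays.

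The transcript of the sorted receptor fell with the inhibitor. Pdgfra, which encodes the receptor used for the sort, was at 9.42 ± 0.07 in untreated cells (log2 mean ± SD, n = 3), 9.55 ± 0.14 with PDGF-AB, 8.51 ± 0.05 with AG1296 1 uM and 9.02 ± 0.03 with AG1296 10 uM. It fell by 0.91 ± 0.09 on the log2 scale (SE) at 1 uM (limma, adjusted p = 3.84e-05) and by less at 10 uM, with a log2 fold change of -0.40 (adjusted p = 0.0361). The difference between doses was 0.51 (adjusted p = 0.0282), and the change with PDGF-AB, 0.13 ± 0.09, did not pass (adjusted p = 0.720). The 10 uM call was lost without any 1 of the AG1296 10 uM or untreated arrays, without any 1 of the AG1296 1 uM arrays and without PDGF-AB replicate 2 (adjusted p up to 0.152), and also with all probe sets, median centring of each array, a fixed replicate block or only the 6 arrays compared (0.0504 to 0.0776). The dose difference was lost without any 1 of the 6 AG1296 arrays (up to 0.134), with median centring (0.0621) and with only the 6 arrays compared (0.0921). Pdgfrb, Kit, Pdgfb and Pecam1 passed in none of the 5 comparisons, and Ly6a, which encodes SCA1, had no probe set under its symbol.

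More genes were called with AG1296 than with PDGF-AB. In the F test over the 4 groups, 997 of 19938 genes differed (limma). The calls against untreated were 66 genes for PDGF-AB, of which 24 were higher and 42 lower, 375 for AG1296 10 uM (241 higher, 134 lower) and 639 for AG1296 1 uM (374 higher, 265 lower). The change was at least 2-fold in 8, 24 and 81 of them. An unadjusted p under 0.05 was seen for 1705, 2276 and 2616 genes, in that order. Groups that did not overlap made up 13.3%, 18.0% and 20.3% of all genes, where chance gives 10%.

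**Figure D1:**
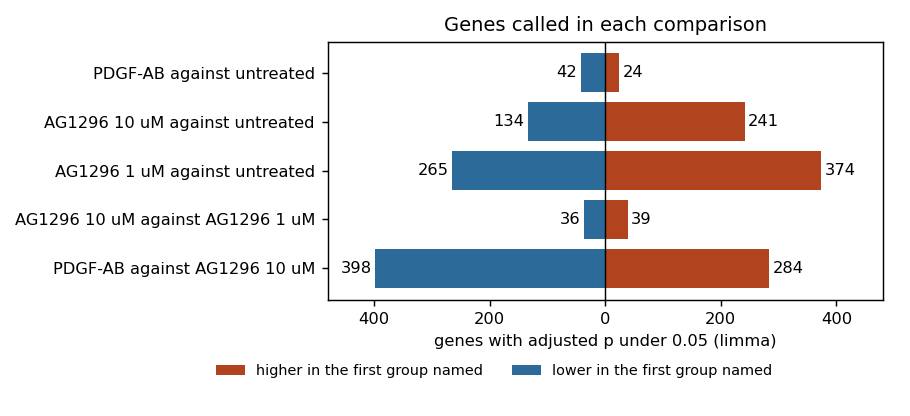
Bars give the number of genes called (limma, adjusted p under 0.05) as higher and as lower in each of the 5 comparisons, from 0. The counts ran from 66 genes for PDGF-AB against untreated to 682 for PDGF-AB against AG1296 10 uM.

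The comparison of PDGF-AB with untreated cells asked which genes the ligand changed in culture. Mgp, which encodes a matrix protein that inhibits calcification, rose from 7.38 ± 0.10 to 8.68 ± 0.09 (log2 mean ± SD, n = 3), a log2 fold change of 1.30 ± 0.10 (SE; adjusted p = 0.000117). Hgf, a growth factor for epithelial and endothelial cells, rose by 1.20 ± 0.14 (adjusted p = 0.00247), and Nrn1, a protein that promotes neurite growth, by 1.25 ± 0.15 (adjusted p = 0.00255). Falls included Rasgrp3, a Ras activator, at -1.12 ± 0.12 (adjusted p = 0.0014), Bmp6, a ligand of the BMP pathway, at -0.78 ± 0.08 (adjusted p = 0.0014), and Fosb, a subunit of the AP-1 transcription factor, at -0.87 ± 0.10 (adjusted p = 0.00247). Map2, a microtubule-associated protein, fell by 1.02 ± 0.12 (adjusted p = 0.00255), and Adamts5, a protease that degrades aggrecan, by 0.70 (adjusted p = 0.00247). Other rises were those of Cd53, a tetraspanin of leukocytes, at 1.77 ± 0.24 (adjusted p = 0.00584), Prl2c5, a proliferin, at 1.70 ± 0.22 (adjusted p = 0.00522) and Olfml3 at 0.71 ± 0.09 (adjusted p = 0.00503). Cd53 was at 5.52 ± 0.63 against 3.75 ± 0.17 in untreated cells (SD), while the list of 19 macrophage and leukocyte markers did not pass (adjusted p = 0.563). Gca and Lurap1l fell by 0.80 and 0.79. Hgf and Cd53 lay below every array median in untreated cells, Hgf at a mean of 3.41, where background limits the fold change. The count of 66 was 40, 30 and 36 without PDGF-AB replicate 1, 2 and 3, and 21, 22 and 23 without untreated replicate 1, 2 and 3. In a fit of the 6 arrays alone, Cd53, Hgf, Olfml3, Map2, Gca and Adamts5 had adjusted p of 0.0844, 0.0551, 0.0559, 0.0741, 0.0559 and 0.0559.

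For 8 of the large changes with PDGF-AB the call was lost without any of several arrays, while the fold kept its sign and stayed between -1.46 and -0.61 for the falls and between 0.64 and 0.99 for the rises. Ptprz1, a receptor phosphatase, fell by 1.25 ± 0.21 (adjusted p = 0.0234), but had adjusted p of 0.111, 0.119 and 0.0688 without untreated replicate 1, 2 and 3. Serpinb2, an inhibitor of plasminogen activators, rose by 0.77 (adjusted p = 0.0107), with 0.0572 without PDGF-AB replicate 2 and 0.0665 and 0.0632 without untreated replicate 2 and 3. F3, the tissue factor that starts coagulation, fell by 0.74 (adjusted p = 0.0158), with 0.0572 without PDGF-AB replicate 2 and 0.0537, 0.0941 and 0.0829 without untreated replicate 1, 2 and 3. Edn1, the vasoconstrictor endothelin, fell by 0.75 ± 0.12 (adjusted p = 0.0144), with 0.0516, 0.0572 and 0.0531 without PDGF-AB replicate 1, 2 and 3 and 0.0504 and 0.0854 without untreated replicate 1 and 2. Slc38a4, Krt6a, Prkar2b and Nkain4 changed by 0.83, 0.78, 0.76 and -0.79. Leaving out 1 array ended each of these 4 calls: Slc38a4 and Nkain4 without PDGF-AB replicate 1 or 2 or any untreated array (adjusted p up to 0.121 and 0.119), and Prkar2b without PDGF-AB replicate 2 or 3 or untreated replicate 1 or 3 (up to 0.0653). For Krt6a these were PDGF-AB replicate 2 or 3, untreated replicate 2 or 3, AG1296 1 uM replicate 1 or 2 and AG1296 10 uM replicate 2 (up to 0.156), and all probe sets, quantile normalization and median centring ended its call too (0.0502 to 0.0588). Krt6a and Serpinb2 lay below every array median in untreated cells (means of 2.82 and 3.94). In a fit of the 6 arrays alone these 8 genes had adjusted p of 0.0742 to 0.204.

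As a group, the targets of TGF-beta and YAP/SRF, which mark contractile activation, had a mean log2 fold change of -0.10 with PDGF-AB over the 17 measured (camera adjusted p = 0.00497; adjusted p = 0.399 with an estimated correlation). Over all genes 0 rose and 0 fell, and adjusted over the list alone 2 rose and 6 fell. The camera adjusted p was 0.0768 without PDGF-AB replicate 2. Its member Tgfb2 stood at -0.53 (adjusted p = 0.111). The 25 markers of fibroblast identity were shifted up, with a mean of 0.10 (camera adjusted p = 0.0211; adjusted p = 0.265 with an estimated correlation), 0 calls over all genes and 3 rises adjusted over the list alone. The 20 measured genes of sterol synthesis were shifted down, with a mean of -0.09 and 0 calls over all genes (camera adjusted p = 0.0211; adjusted p = 0.405 with an estimated correlation). The identity call was lost without PDGF-AB replicate 3 or untreated replicate 3 (adjusted p up to 0.218), and the sterol call without PDGF-AB replicate 1, untreated replicate 1 or 2 (up to 0.0909), after quantile normalization (0.096) and with dim genes filtered out (0.0827). The list of 28 interstitial matrix genes had a median of 0.05 and a mean of -0.01, which differ in sign, and did not pass (adjusted p = 0.944), nor did ERK pathway feedback (0.178) or mitosis (0.692).

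AG1296 at 10 uM was compared with untreated cells to see which genes the inhibitor changed without added ligand. Fndc1, a fibronectin type III domain protein, rose by 1.70 ± 0.09 (log2 fold change ± SE, n = 3; adjusted p = 6.88e-07), Kif26b, a kinesin family member, by 1.38 ± 0.12 (adjusted p = 3.31e-05), and Scn7a, a sodium channel, by 1.45 ± 0.13 (adjusted p = 5.42e-05). The secreted Wnt antagonists Sfrp1 and Sfrp2 rose by 1.29 ± 0.09 (adjusted p = 6.63e-06) and 1.67 ± 0.28 (adjusted p = 0.00545). Nqo1, a quinone reductase, fell by 1.77 ± 0.12 (adjusted p = 6.2e-06), Ptgs2, the inducible cyclooxygenase, changed by -1.70 ± 0.10 (adjusted p = 1.66e-06), and Esm1, an endothelial proteoglycan also made by other cells, fell by 1.96 ± 0.18 (adjusted p = 5.42e-05). Nrn1 and Mgp, which rose with PDGF-AB, fell by 1.59 and 0.82, and Prl2c5 fell by 2.49, to a mean of 2.10 that lay below every array median, whereas Map2 rose by 1.06. The other large rises were those of Lama4 (1.21), Grb14 (1.17), Rgs4 (1.12) and Galnt16 (1.07), and the other large falls those of Cd24a (-1.57), Ch25h (-1.44), Upk1b (-1.13), S1pr3 (-1.12) and Pla2g4a (-1.09). The count of 375 was 229 and 219 without AG1296 10 uM replicate 1 and 2, and 245, 234 and 227 without untreated replicate 1, 2 and 3.

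Interstitial collagens and matrix formed the clearest group at 10 uM. Of its 28 measured genes 14 rose and 0 fell over all genes, 21 and 0 adjusted over the list alone, and 27 were higher (mean log2 fold change 0.37; camera adjusted p = 2.82e-21, and 0.0131 with an estimated correlation). Examples were Mfap4, a microfibril protein, at 0.82 (adjusted p = 0.000153), the small proteoglycan Dcn at 0.75 (adjusted p = 0.00155), Postn at 0.68 (adjusted p = 0.00381) and Col14a1 at 0.62 (adjusted p = 0.00115). Among 12 basement membrane genes 4 rose and 0 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 1.87e-07; adjusted p = 0.0844 with an estimated correlation). They were led by Lama4 and by Col4a1 at 0.63 (adjusted p = 0.0033). In the Wnt list 7 of 21 rose and 2 fell, 8 and 4 adjusted over the list alone (camera adjusted p = 0.00411; adjusted p = 0.0698 with an estimated correlation). Among those that rose, Sfrp1, Sfrp2 and Apcdd1 (0.94) are known inhibitors of Wnt signalling, and Dkk2, which fell by 0.74 (adjusted p = 0.00328), is a Wnt modulator.

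Falls at 10 uM were found in part of 4 lists. In the NRF2 oxidative stress list 6 of 16 fell and 0 rose, 7 and 0 adjusted over the list alone (mean -0.34; camera adjusted p = 3.45e-08; adjusted p = 0.0552 with an estimated correlation). Its member Hmox1, which degrades heme, stood at -0.99 (adjusted p = 0.000119). Of 25 immediate early genes 4 fell and 0 rose, 6 and 0 adjusted over the list alone (camera adjusted p = 2.55e-06, and 0.0419 with an estimated correlation). Among them were Fosb (-0.84) and Plaur, the urokinase receptor (-0.80). Fosb was also called as lower with PDGF-AB and at AG1296 1 uM, so its fall was not particular to the inhibitor. In the ERK feedback list 2 of 19 fell and 0 rose, 8 and 0 adjusted over the list alone (camera adjusted p = 9.73e-05, and 0.0397 with an estimated correlation). Dusp6, the phosphatase that inactivates ERK, fell by 0.78 (adjusted p = 0.000647). The 8 aryl hydrocarbon receptor targets held 2 falls, Nqo1 and Cyp1b1 (-0.51), and 0 rises, 3 and 0 adjusted over the list alone (camera adjusted p = 5.66e-05, and 0.0357 with an estimated correlation). Nqo1 belongs to this list and to the NRF2 list.

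Lists of lipid synthesis and of ATF4 and unfolded protein response genes were shifted up at 10 uM with few single calls. Fatty acid synthesis held 0 calls among 11 genes and 5 rises adjusted over the list alone (mean 0.18; camera adjusted p = 7e-05; adjusted p = 0.0844 with an estimated correlation). The ATF4 list covers amino acid stress and the unfolded protein response. It had 1 rise and 0 falls of 25, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00284, and adjusted p = 0.210 with an estimated correlation). For sterol synthesis 0 of 20 passed by either adjustment, 16 were higher and the mean was 0.12 (camera adjusted p = 0.0105; adjusted p = 0.371 with an estimated correlation). That call was lost without AG1296 10 uM replicate 2 or untreated replicate 3 (adjusted p up to 0.140).

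With AG1296 at 1 uM, matrix genes were again higher than in untreated cells. Dcn went from 7.64 ± 0.04 to 9.35 ± 0.17 (log2 mean ± SD, n = 3), a change of 1.71 ± 0.10 (SE; adjusted p = 8.21e-07). Lum, another small proteoglycan of collagen fibrils, rose by 1.91 ± 0.13 (adjusted p = 2.1e-06), and Mfap4 by 1.56 ± 0.09 (adjusted p = 4.9e-07). Fndc1 went from 5.60 ± 0.03 to 7.60 ± 0.11 (SD; adjusted p = 8.55e-08), and Fibin rose by 1.83 ± 0.09 (adjusted p = 2.33e-07) and Scn7a by 2.09 ± 0.13 (adjusted p = 9.68e-07). Npy1r, a receptor of neuropeptide Y, rose by 1.92 ± 0.13 (adjusted p = 1.22e-06), and Cdo1, Rgs4 and Svep1 by 1.58, 1.47 and 1.41. Falls included Nrn1 at -2.67 ± 0.15 (adjusted p = 5.38e-07), Nqo1 at -1.81 ± 0.12 (adjusted p = 1.15e-06), Dkk2 at -1.54 (adjusted p = 2.75e-06) and S1pr3, a receptor of sphingosine-1-phosphate, at -1.74 (adjusted p = 5.55e-07). Prl2c5, Cd24a, Plac8, Esm1 and Tll1 fell by 2.77, 2.01, 1.69, 1.68 and 1.55. Mcam, an adhesion molecule of perivascular cells, fell by 1.42 (adjusted p = 1.15e-06), and the chemokine Cxcl12 by 1.10 (adjusted p = 9.5e-06). Rny3, a Y RNA, fell by 2.55 ± 0.55 (adjusted p = 0.0201), but not without any 1 of the 6 arrays compared (up to 0.0743) or with an intensity trend and robust moderation (0.0926). Background limits the fold change of genes below every array median, which were Lum and Npy1r in untreated cells (2.49 and 2.72) and Prl2c5, Cd24a and Dkk2 at 1 uM (1.82, 3.78 and 3.87). The count of 639 was 349 and 383 without AG1296 1 uM replicate 1 and 2, and 390, 405 and 397 without untreated replicate 1, 2 and 3.

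**Figure D2:**
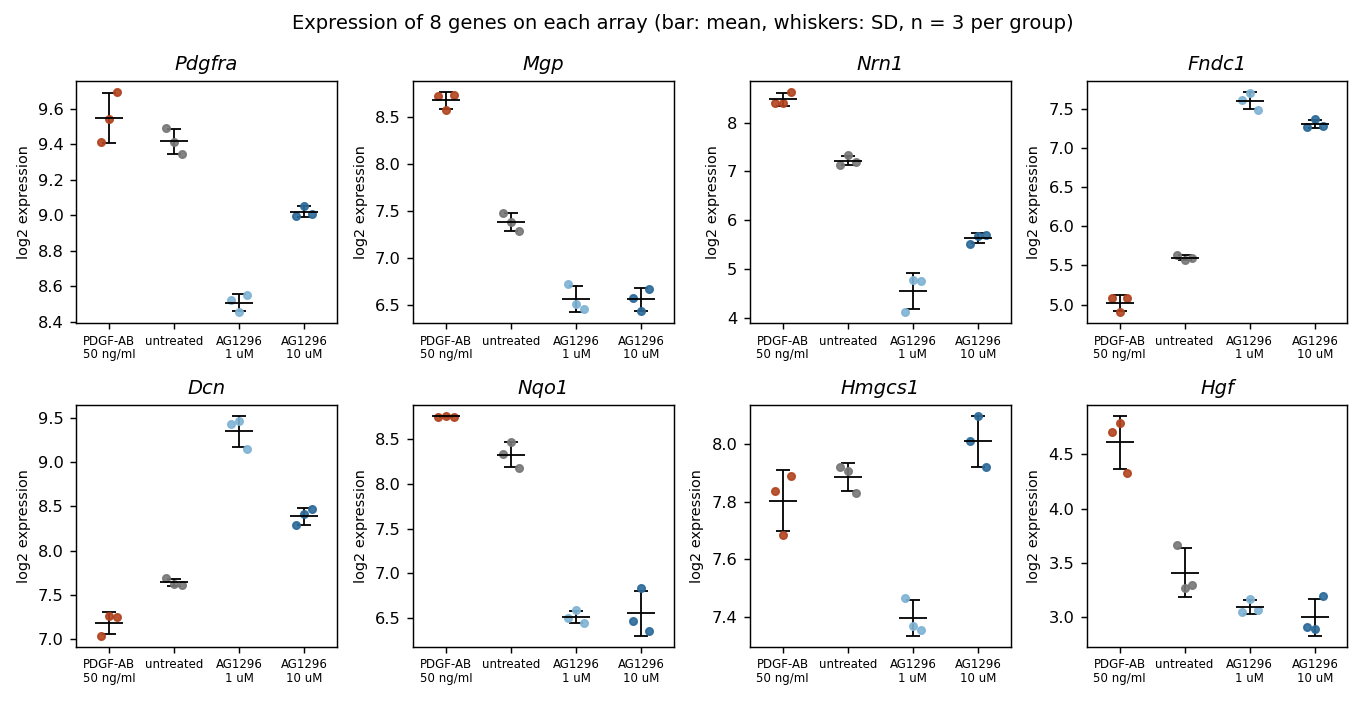
Points are log2 expression on each array for 8 genes in the 4 groups, and lines with bars are the mean ± SD of 3 arrays. Mgp and Nrn1 were higher with PDGF-AB and lower with AG1296 than in untreated cells, and Dcn was highest at AG1296 1 uM.

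Of the 28 interstitial matrix genes, 13 rose and 1, Tnc, fell at 1 uM, 19 and 1 adjusted over the list alone (mean log2 fold change 0.46; camera adjusted p = 6.26e-19, and 0.0131 with an estimated correlation). Among the 25 genes of the ATF4 and unfolded protein response list 3 rose and 0 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 1.25e-08, and 0.0419 with an estimated correlation). They included the amino acid transporter Slc7a5 at 0.73 (adjusted p = 0.000557) and Trib3 at 0.70 (adjusted p = 0.00458). In the ERK feedback list 6 of 19 fell and 1 rose, 9 and 2 adjusted over the list alone (camera adjusted p = 0.000545, and 0.0494 with an estimated correlation). Dusp6 was at -0.64 (adjusted p = 0.00198) and the G1 cyclin Ccnd1 at -0.63 (adjusted p = 0.000296). Sterol synthesis was lower, with 2 falls and 0 rises of 20, 0 rises and 7 falls adjusted over the list alone (mean -0.20; camera adjusted p = 5.54e-05; adjusted p = 0.160 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell by 0.49 (adjusted p = 0.00581). Basement membrane held 4 rises and 1 fall of 12, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0021; adjusted p = 0.265 with an estimated correlation). Lama4 rose by 1.07 and Nid1 fell by 0.63.

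Of 8 aryl hydrocarbon receptor targets 2 fell and 0 rose at 1 uM, 2 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.0844 with an estimated correlation). Cyp1b1, a cytochrome P450, fell by 1.01 (adjusted p = 6.43e-06). Wnt genes gave 5 rises and 1 fall of 21, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0157, 0.0631 without untreated replicate 2; adjusted p = 0.1 with an estimated correlation). Schwann and neural markers gave 1 rise of 8, Ncam1 at 0.72 (adjusted p = 0.000761), and 2 adjusted over the list alone (camera adjusted p = 0.0259, 0.0872 without AG1296 1 uM replicate 3 and 0.221 with dim genes filtered out; adjusted p = 0.157 with an estimated correlation). Immediate early genes gave 5 falls of 25 and 8 adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.266 with an estimated correlation). This call was lost without AG1296 1 uM replicate 3 or untreated replicate 2 (up to 0.233). The NRF2 list, with 3 falls and 1 rise over all genes, did not pass at 1 uM (adjusted p = 0.0643).

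Short noncoding RNAs, a class chosen after the values were seen, were lower on the AG1296 1 uM arrays beside these changes. Their 70 genes averaged 4.68 ± 0.07 in untreated cells (log2 mean ± SD, n = 3), 4.67 ± 0.11 with PDGF-AB, 4.29 ± 0.03 at 1 uM and 4.47 ± 0.19 at 10 uM. At 1 uM 15 fell and 0 rose (camera adjusted p = 1.69e-09 over 20 tests of such classes; adjusted p = 0.110 with an estimated correlation). The 15 falls were 6, 8 and 8 without AG1296 1 uM replicate 1, 2 and 3, and 7, 6 and 8 without untreated replicate 1, 2 and 3. Of 26 replication-dependent histone genes, whose transcripts lack a poly(A) tail, 9 fell and 0 rose, with a mean of -0.40 (camera adjusted p = 1.02e-15; adjusted p = 0.0764 with an estimated correlation). The 9 were 5 without untreated replicate 2. At 10 uM the means were -0.20 and -0.24, with camera adjusted p of 1.64e-05 and 7.13e-09 (adjusted p = 0.244 and adjusted p = 0.110 with an estimated correlation). The short noncoding mean was -0.31, with 12 falls in place of 0, without AG1296 10 uM replicate 3, and -0.13 without replicate 2. The 8 replication-independent histone genes had a mean of -0.02 at 1 uM (adjusted p = 0.719). The 297 microRNA precursors, at a mean level of 2.99 in untreated cells, had a mean of -0.08 at 1 uM (camera adjusted p = 0.0064; adjusted p = 0.620 with an estimated correlation). That call was lost without AG1296 1 uM replicate 2 (mean -0.04, adjusted p = 0.106) or untreated replicate 3 (0.0852). At 1 uM the short noncoding and the replication-dependent histone means kept their sign after quantile normalization (-0.38 and -0.40) and median centring (-0.39 and -0.40).

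The doses of AG1296 were compared with each other to test whether the response depended on dose. At 10 uM the sterol genes were higher than at 1 uM, while matrix genes went both ways, several of them lower and Col6a1 higher. Lum differed by -1.96 ± 0.13 (log2 fold change ± SE, n = 3; adjusted p = 1.22e-05), Fibin by -1.53 ± 0.09 (adjusted p = 4.68e-06), Npy1r by -1.42 (adjusted p = 0.000216) and Cdo1 by -1.16 (adjusted p = 0.000553). Lum and Npy1r lay below every array median at 10 uM (2.43 and 3.21), and Dkk2 at 1 uM (3.87). Also lower were Peg10 by -1.04 (adjusted p = 0.000216), Dcn by -0.96 (adjusted p = 0.000998) and Mfap4 by -0.75 (adjusted p = 0.00145). The matrix gene Col6a1 was called as higher, by 0.45 to 0.55 in fits that left out 1 array. Its call was lost in 6 of these 12 fits (limma adjusted p up to 0.121). Mcam was higher by 0.83 ± 0.09 (adjusted p = 0.0011), Nrn1 by 1.08 ± 0.15 (adjusted p = 0.00778, 0.0518 without AG1296 10 uM replicate 3) and Dkk2 by 0.80 ± 0.11 (adjusted p = 0.00778, 0.0518 without AG1296 1 uM replicate 2). In all, 75 genes differed, 39 higher and 36 lower at 10 uM, of which 6 by at least 2-fold. Of these 52.0% were higher, and 40.4% with each array centred on its median. In a fit of the 6 arrays alone Nrn1 had an adjusted p of 0.0821. An unadjusted p under 0.05 was seen for 1809 genes, and groups did not overlap for 15.9% against 10% by chance. The count was 26, 16 and 29 without AG1296 1 uM replicate 1, 2 and 3, 16, 39 and 19 without AG1296 10 uM replicate 1, 2 and 3, and 49 without untreated replicate 2.

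All 20 measured sterol synthesis genes were higher at 10 uM than at 1 uM, with a mean difference of 0.31. Of them 3 passed over all genes and 14 adjusted over the list alone (camera adjusted p = 1.39e-14, and 0.0357 with an estimated correlation). Hmgcs1 was higher by 0.61 (adjusted p = 0.00822), but had adjusted p of 0.0579 without AG1296 1 uM replicate 2 and 0.055 without AG1296 10 uM replicate 1. Fdps and Nsdhl, at 0.53 and 0.51, did not pass with each array centred on its median (0.0685 and 0.1) or without any 1 of AG1296 1 uM replicates 1 to 3 or AG1296 10 uM replicate 1 or 2, nor without several of the other arrays (up to 0.174 and 0.192). Fatty acid synthesis gave 1 rise of 11, Scd2 at 0.65 (adjusted p = 0.00724, 0.0522 without AG1296 10 uM replicate 1), and 2 adjusted over the list alone (camera adjusted p = 9.17e-05; adjusted p = 0.0854 with an estimated correlation). In the NRF2 list 2 of 16 were lower and 0 higher, 3 and 0 adjusted over the list alone (camera adjusted p = 0.000191; adjusted p = 0.160 with an estimated correlation). The cystine transporter Slc7a11 was at -0.92 (adjusted p = 0.00491). In a fit of the 6 arrays alone Hmgcs1, Fdps, Nsdhl and Scd2 had adjusted p of 0.0732, 0.098, 0.185 and 0.0782.

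Smaller shifts between the doses were seen in 4 other lists. The ATF4 list had a mean of -0.12, 0 calls and 1 fall adjusted over the list alone (camera adjusted p = 0.000367; adjusted p = 0.160 with an estimated correlation). Basement membrane had a mean of 0.14, 1 rise of 12, and 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.350 with an estimated correlation). Pericyte markers had a mean of 0.18, with Mcam the 1 rise of 12 and 3 adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.210 with an estimated correlation). Immediate early genes had a mean of -0.07, 0 calls and 1 fall adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.229 with an estimated correlation). Single arrays ended the last 3 calls: AG1296 1 uM replicate 3 or AG1296 10 uM replicate 3 for basement membrane (up to 0.0803), replicate 2 of either dose for pericyte markers (up to 0.086), and AG1296 1 uM replicate 1 or 2 or AG1296 10 uM replicate 2 for immediate early genes (up to 0.0737), which quantile normalization (0.0869) and a filter on dim genes (0.0827) also ended. Interstitial matrix, with a median of 0.01 and a mean of -0.09 that differ in sign, did not pass (adjusted p = 0.204).

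**Figure D3:**
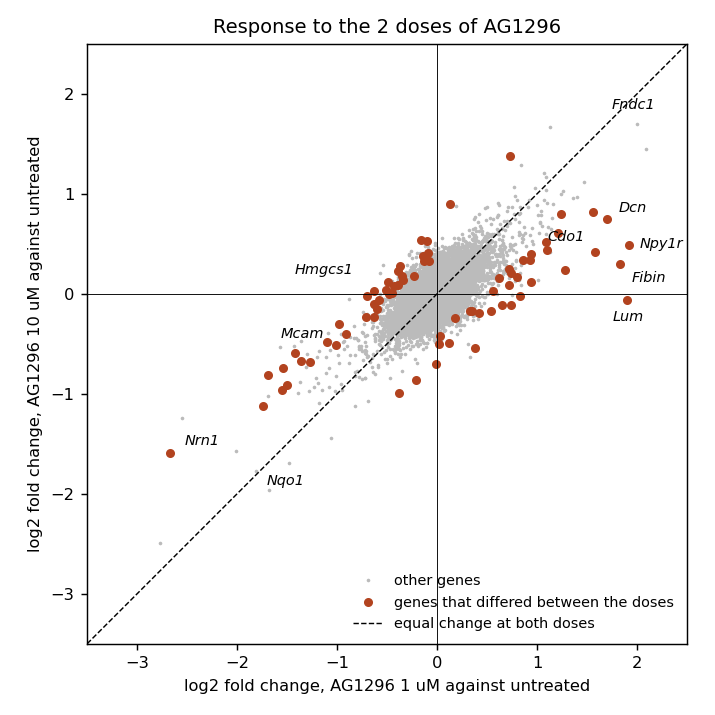
Each point is a gene, with its log2 fold change against untreated at AG1296 1 uM on the x axis and at 10 uM on the y axis, and the 75 genes that differed between the doses are in red. For 59 of these 75 genes, 10 uM lay closer to untreated than 1 uM.

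Most genes called at 10 uM had the same sign at 1 uM, 367 of 375. The doses share the untreated arrays, which alone gave the same sign for 66.6% of all genes in simulated unchanged groups. That share was not taken over called genes. The slope of the 1 uM on the 10 uM change across genes was 1.00 and the median ratio 0.907 for genes called at 10 uM. These were 1.25 and 1.47 for the 639 called at 1 uM, so that they depend on which dose selects the genes, and 1.13 and 1.18 for the 660 called in the mean of both doses. Both doses called 256 genes, all with the same sign, while 119 were called at 10 uM alone and 383 at 1 uM alone, a difference in calls that is tested only by the comparison of the doses. Of the 75 genes that differed between doses, 10 uM lay closer to untreated for 59, such as Lum, Dcn and Nrn1, and farther on the same side for 5. Of these 660 genes, a set chosen after the values were seen, 65.3% moved farther at 1 uM. Of them 43 differed between the doses, 39 with the larger change at 1 uM and 4 at 10 uM. The share that moved farther at 1 uM was 41.6% of genes called at 10 uM and 83.4% of genes called at 1 uM.

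PDGF-AB was set against AG1296 10 uM to contrast ligand with inhibitor. Here 682 genes differed, 284 higher and 398 lower with PDGF-AB, 78 by at least 2-fold, with an unadjusted p under 0.05 for 2813 and no overlap for 18.1% of genes (10% by chance). Nrn1 was higher with PDGF-AB by 2.84 ± 0.15 (log2 fold change ± SE, n = 3; adjusted p = 1.7e-07), Nqo1 by 2.20 ± 0.12 (adjusted p = 1.7e-07) and Mgp by 2.12 (adjusted p = 1.15e-07). Prl2c5 was higher by 4.19 ± 0.22 (adjusted p = 1.7e-07), Cd53 by 2.23 ± 0.24 (adjusted p = 6.73e-05) and Esm1 by 2.19 ± 0.18 (adjusted p = 7.02e-06). Prl2c5 and Cd53 lay below every array median at AG1296 10 uM (2.10 and 3.29), where background limits the fold change. Fndc1 was lower by -2.28 ± 0.09 (adjusted p = 1.56e-08), Map2 by -2.08 ± 0.12 (adjusted p = 3.86e-07), Ptprz1 by -2.02 ± 0.21 (adjusted p = 6.46e-05), Sfrp2 by -1.88 (adjusted p = 0.00111) and Scn7a by -1.82 (adjusted p = 2.17e-06). The growth factor Tgfb2 was lower by -1.33 (adjusted p = 1.72e-05) and Adamts5 by -1.36 (adjusted p = 4.17e-07). Pdgfd, a further PDGF ligand, was lower by -0.60 (adjusted p = 0.00111), and Ptgs2 was higher by 1.98 (adjusted p = 1.47e-07).

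Matrix genes were lower with PDGF-AB than with AG1296 10 uM: 11 of 28 were lower and 1, Tnc, which encodes tenascin-C, higher, 18 and 2 adjusted over the list alone (mean -0.39; camera adjusted p = 5.95e-15, and 0.0199 with an estimated correlation). Examples were Dcn at -1.21, Ogn at -1.16 and Col12a1 at -1.09. In the NRF2 list 7 of 16 were higher and 1, Gstm1, lower, 10 and 1 adjusted over the list alone (camera adjusted p = 1.7e-09, and 0.0419 with an estimated correlation). Hmox1 was at 0.98 and Slc7a11 at 0.77. ERK feedback held 8 higher and 0 lower of 19, 10 and 0 adjusted over the list alone (camera adjusted p = 2.22e-05, and 0.0357 with an estimated correlation). Dusp6 was at 0.81, Spred1 at 0.59 and the protease Mmp3 at 0.90. The aryl hydrocarbon receptor list held 2 higher of 8 and 4 adjusted over the list alone (camera adjusted p = 4.86e-06, and 0.0306 with an estimated correlation). Immediate early genes held 6 higher and 1, Fos, lower of 25, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0003; adjusted p = 0.0854 with an estimated correlation). Plaur was at 0.92 and the AP-1 subunit Fosl1 at 0.84. The fall of Fos was lost without AG1296 10 uM replicate 3 (adjusted p = 0.0711) or PDGF-AB replicate 1 or 3 (0.0505 and 0.0556) and with the 6 arrays alone (0.0785). Against untreated, each list of this paragraph passed with AG1296 10 uM and none passed with PDGF-AB.

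Sterol synthesis genes were lower with PDGF-AB than with AG1296 10 uM, with 2 lower of 20 and 6 adjusted over the list alone (mean -0.21; camera adjusted p = 1.67e-05; adjusted p = 0.157 with an estimated correlation). Basement membrane held 6 lower and 1, Nid1, higher of 12, 8 and 2 adjusted over the list alone (camera adjusted p = 9.17e-05; adjusted p = 0.160 with an estimated correlation). Lama4 was at -0.93. In the ATF4 list 4 of 25 were lower, 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000154; adjusted p = 0.144 with an estimated correlation). Fatty acid synthesis held 2 lower of 11, 3 adjusted over the list alone (camera adjusted p = 0.00309; adjusted p = 0.160 with an estimated correlation). The desaturase Fads2 was at -0.53. Myofibroblast genes held 3 lower of 22, and 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00748; adjusted p = 0.160 with an estimated correlation). Actn1 was at -0.41. Wnt genes held 5 lower, among them Sfrp1 (-1.31) and Ccn5 (-1.38), and 2 higher of 21, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0212; adjusted p = 0.120 with an estimated correlation). DNA replication had a mean of 0.09, with 1 lower of 33, and 1 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.399 with an estimated correlation). Fibroblast identity held 4 higher and 1 lower of 25, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.298 with an estimated correlation). The last pair of calls was lost without AG1296 10 uM replicate 1 or 3 or PDGF-AB replicate 1 for DNA replication (up to 0.136), and without AG1296 10 uM replicate 3 or PDGF-AB replicate 3 for identity (up to 0.169), whose adjusted p was 0.0515 with dim genes filtered out. In a fit of the 6 arrays alone Actn1 had an adjusted p of 0.0749.

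**Figure D4:**
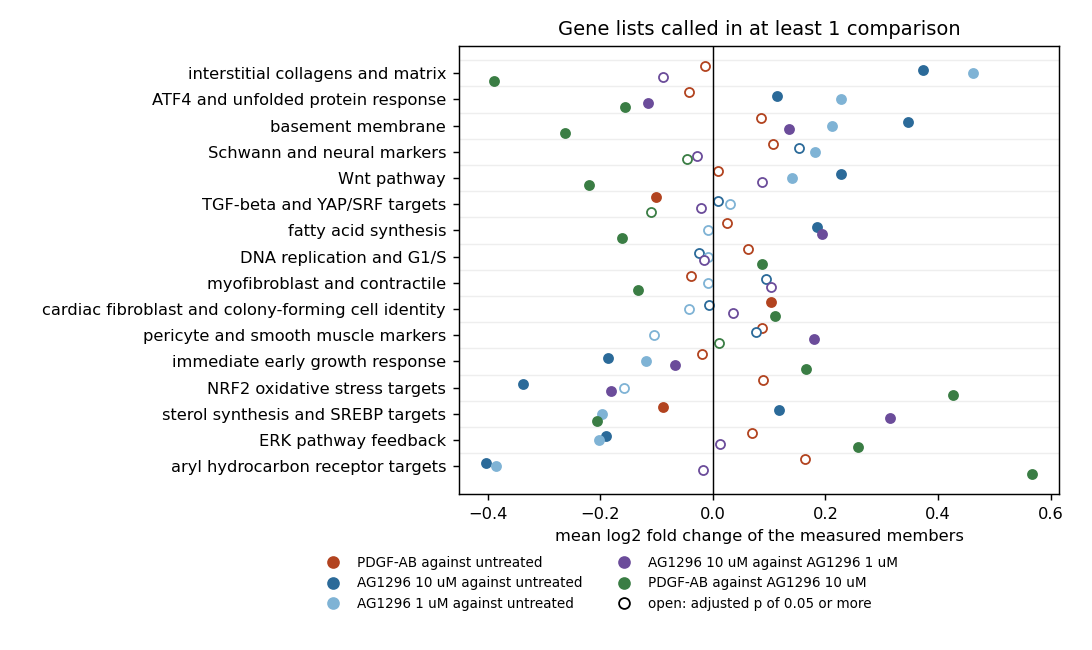
Each point is the mean log2 fold change of the measured members of a list, for the 16 lists called in at least 1 of the 5 comparisons, with open points where camera did not pass. The interstitial matrix list lay at 0.37 and 0.46 with AG1296 10 uM and 1 uM against untreated, and at -0.39 for PDGF-AB against AG1296 10 uM.

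Genes called with both ligand and inhibitor mostly moved in opposite directions. PDGF-AB and AG1296 10 uM, each against untreated, shared 32 called genes, of which 28 had opposite signs, as for Mgp, Nrn1 and Map2, and 4 the same, where independent lists would share 0.669 and 0.572. With AG1296 1 uM it was 37 of 42, a count not recomputed with arrays left out. Over all genes called with the inhibitor, called with PDGF-AB or not, 183 of 375 (48.8%) at 10 uM and 345 of 639 (54.0%) at 1 uM had the opposite sign with PDGF-AB. Because the untreated arrays are shared, simulated unchanged groups had the same sign for 66.6% and 66.7% of all genes. These genes were simulated without any response, so they give no expected value for genes selected by a response to AG1296. Nothing is concluded from the shares of 48.8% and 54.0%. Across all genes, which are not independent replicates, the fold changes of PDGF-AB and AG1296 10 uM correlated at r = 0.229 (rho = 0.329), below the 0.499 that simulated unchanged groups sharing the untreated arrays gave. This r was 0.361 without untreated replicate 3 and 0.0986 with dim genes filtered out, and a response to either treatment alone would also lower it. For the doses of AG1296 r was 0.655. The 28 opposite genes were 18 and 18 without AG1296 10 uM replicate 1 and 2, 12 and 13 without PDGF-AB replicate 2 and 3, and 8, 9 and 9 without untreated replicate 1, 2 and 3.

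The remaining lists passed in none of the 5 comparisons. Among markers of other cell types, the calls of the pericyte list between the doses and of the Schwann list at 1 uM were both lost with an estimated correlation (adjusted p = 0.210 and adjusted p = 0.157 with an estimated correlation). The smallest camera adjusted p over the comparisons was 0.501 for 18 endothelial markers, 0.563 for 19 macrophage and leukocyte markers, 0.407 for 15 cardiomyocyte markers and 0.0816 for 13 epicardial and mesothelial markers. It was 0.155 for 34 mitosis genes, 0.227 for 21 ribosomal proteins, 0.0502 for 23 genes of oxidative phosphorylation, 0.152 for 23 of glycolysis and hypoxia, 0.109 for 18 p53 targets and 0.185 for 22 FOXO and quiescence genes. Adipogenic and osteo-chondrogenic genes reached 0.141 and 0.122, interferon response 0.419, complement 0.394, chemokines and cytokines 0.154, and matrix proteases and inhibitors 0.0723. For the 7 PDGF receptors and ligands it was 0.171, and for 6 other kinases that AG1296 is known to bind 0.227. Single members changed within these lists. Among mesothelial markers Upk1b fell by 1.13 (adjusted p = 2.09e-05) at 10 uM and 0.82 (adjusted p = 0.000109) at 1 uM, Lrrn4 fell by 0.84 (adjusted p = 0.00545) at 10 uM, and Upk3b rose by 0.55 (adjusted p = 0.00511) at 1 uM. C3ar1, a complement receptor of myeloid cells, fell by 1.23 (adjusted p = 0.00145) at 1 uM, and Tek, an endothelial receptor kinase, rose by 0.73 (adjusted p = 0.000761) at 1 uM. Tek lay below every array median in untreated cells (3.52) and C3ar1 at 1 uM (3.63). Other examples were the protease inhibitor Timp3, which rose by 0.79 (adjusted p = 0.000177) at 10 uM and 1.01 (adjusted p = 8.54e-06) at 1 uM, and Sox9, a regulator of chondrogenesis, which rose by 0.76 (adjusted p = 0.000264) and 0.53 (adjusted p = 0.00273).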

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

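The counts over other splits of the arrays were planned; the tests of scale, of a common factor, of exchanged dose labels, of noise in the untreated arrays, of graded expression, and of histone and DNA replication genes were chosen after the results were seen.

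A direct test found differences between the doses of AG1296: 75 genes differed between 10 uM and 1 uM (limma), and the sterol synthesis list was higher at 10 uM by a mean of 0.314 on the log2 scale, with 14 of its 20 genes higher adjusted over the list alone. The count fell to 26, 16 and 29 without AG1296 1 uM replicate 1, 2 and 3, to 16, 39 and 19 without AG1296 10 uM replicate 1, 2 and 3, and to 49 without untreated replicate 2. Probe sets without a single gene symbol, which the comparisons leave out, also held signal. Among these 7064 probe sets the calls were 5 for PDGF-AB against untreated (5 higher, 0 lower), 26 for AG1296 10 uM (11 higher, 15 lower), 94 for AG1296 1 uM (22 higher, 72 lower), 5 between the doses (3 higher, 2 lower) and 45 between PDGF-AB and AG1296 10 uM (26 higher, 19 lower).

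In each comparison of 3 against 3 arrays, 1 of the 10 splits of the 6 arrays, the real one, called as many genes as were reported. The real counts were 66, 375, 639 and 75 for PDGF-AB, AG1296 10 uM and AG1296 1 uM against untreated and for the doses, with 0 as the highest of the other splits, and 682 for PDGF-AB against AG1296 10 uM, with 1 as the highest other. These splits are too few for a share under 0.05. For the F test over the 4 groups, 1 of 100 random splits of the 12 arrays, the real one, called as many as 997 genes. The highest other called 57, which argues against chance differences between single arrays there, as far as 100 splits can. The other splits mix arrays of different treatments, which widens the spread within their groups and lowers their counts. Chance differences between cultures cannot be excluded, since the labels do not say whether the arrays of a group came from separate cultures.

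The first pattern is the larger response to AG1296 at the lower dose: 65.3% of 660 responsive genes, called in the mean of both doses, moved farther at 1 uM. The share depends on the selection, with 41.6% for genes called at 10 uM and 83.4% for genes called at 1 uM. The values had already been normalized across arrays by RMA, so only a remaining difference in scale or centring could be tested. Such a remaining difference is argued against. The share of 65.3% became 63.5% after quantile normalization and 65.8% after median centring. Its SD of 2.09 over fits that left out single arrays is not a standard error of the share. A response that was weaker at 10 uM by 1 factor (0.814) for all genes is argued against too, because 111 genes (16.8%) departed from it, 57 of them farther from untreated at 10 uM than the factor gives, such as Sfrp1 and Kif26b, and 54 nearer, such as Lum and Dcn. Exchanged dose labels cannot be told apart from a true order by these data, as the labels alone give the order. Of the 43 genes among these 660 that differed between the doses, 39 lay farther from untreated at 1 uM and 4 at 10 uM. A dose effect of AG1296 itself, for instance through other kinases, was not tested.

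The second pattern is the opposite movement of genes called with both PDGF-AB and AG1296 10 uM, 28 of 32 (18 and 18 without AG1296 10 uM replicate 1 and 2, 12 and 13 without PDGF-AB replicate 2 and 3, and 8, 9 and 9 without untreated replicate 1, 2 and 3). Noise in the shared untreated arrays pushes both fold changes the same way, so as the cause of opposite calls it is argued against by 28 opposite against 4 equal signs among genes called in both, which were selected without regard to sign. Graded expression, with untreated cultures between ligand and inhibitor, was consistent with the data: the untreated mean lay between both treatments for 84.6% of the 682 genes called between them, and for at least 82.7% without any 1 untreated array. Data simulated with a response to AG1296 only gave at most 72.1%, and to PDGF-AB only at most 78.6%. There were 20 data sets of each kind, with noise independent between genes. Deviations shared by many genes could widen these ranges, and PDGF-AB and AG1296 arrays were not left out here. That untreated cultures may carry some PDGF receptor activity is a hypothesis, which the arrays do not measure.

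The third pattern is the lower level of short noncoding RNAs on the AG1296 1 uM arrays, with 15 of 70 lower and a mean of -0.39 (6, 8 and 8 lower without AG1296 1 uM replicate 1, 2 and 3, and 7, 6 and 8 without untreated replicate 1, 2 and 3). Less short or non-polyadenylated RNA in the labelled material could lower the replication-dependent histone genes as well. These had a mean of -0.404 (camera adjusted p = 0.0764 with an estimated correlation). A change in the cells could lower them too, so this class cannot tell these explanations apart at any p-value. Fewer cells copying their DNA would lower the DNA replication list, but its 33 genes had a mean of only -0.00874. The SE of 0.029 over members treats genes as independent and does not measure the spread between arrays. For the histone part this explanation is therefore not excluded, though the list hardly changed on these arrays. A further class of short RNA, the 297 microRNA precursors, had a mean of only -0.08 at 1 uM, but at a level of 2.99, below every array median, it decides nothing. A biological effect of the inhibitor on these RNAs was not tested.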

How the results depend on the processing

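The settings were planned, except those for the percent of genes that moved farther at 1 uM, which were chosen after seeing the data. Counts are given in the order F test, PDGF-AB, AG1296 10 uM and AG1296 1 uM against untreated, AG1296 10 uM against 1 uM, and PDGF-AB against AG1296 10 uM. An intensity trend with robust moderation gave 1610, 160, 686, 1010, 209 and 1077 genes, and an adjusted p under 0.01 gave 557, 18, 189, 309, 20 and 377. A 2-fold minimum left 8, 24, 81, 6 and 78 in the 5 comparisons. With dim genes filtered out, which left 11386 to test, PDGF-AB gave 114, AG1296 10 uM 626 and the doses 150, the slope of the 1 uM on the 10 uM changes was 0.983, and r between PDGF-AB and AG1296 10 uM was 0.0986. Only the 6 arrays compared gave 7 for PDGF-AB, 218 for AG1296 10 uM, 14 for the doses and 391 for PDGF-AB against AG1296 10 uM, with fewer arrays to estimate the spread, and array weights gave 146 for the doses. For the other settings that moved counts the cause was not tested. Leaving out 1 array gave 731 to 901, 21 to 62, 219 to 434, 349 to 718, 16 to 82 and 455 to 627 genes, a slope of 0.99 to 1.03, r of 0.199 to 0.361, 8 to 23 genes with opposite signs, 2 to 4 with the same sign, and 60.7% to 67.9% of genes farther at 1 uM. The replicate number as a fixed block gave 1051, 61, 391, 666, 77 and 724 genes and as a random block 1194, 92, 442, 779, 105 and 801. The labels do not say that it pairs arrays. Of 18 same-numbered pairs 9 correlated above 0.1 (-0.0307 to 0.298), and 8 of 12 arrays correlated best with their own number. The range was -0.016 to 0.0651 for number 1, 0.154 to 0.298 for number 2 and -0.0307 to 0.217 for number 3. Arrays numbered 2 thus shared a deviation across groups, which the main fit does not model.

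None of the named genes or lists that passed reversed under these settings. Of 296 passing results for named genes, 120 lost the call at least once, in 839 of 6502 values: 98 with only the 6 arrays compared, 37 with all probe sets, 35 with median centring, 18 with a fixed block, 11 after quantile normalization, 4 with array weights, 1 with the trend, and 31 to 65 without single arrays. Of 42 list calls, 30 lost it at least once, 30 of them with an estimated correlation, and 60 of 714 values were past the threshold no more. Named genes that did not pass were not refitted. Kit and Pecam1 lay below the array medians, where signal over background limits what a fall can show.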

Other observations

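The genes in this part were chosen after their values were seen, from secreted factors and regulators outside the fixed lists or not yet described, and no tests were planned for them.

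Of 45 genes looked at, 21 were called at either dose of AG1296 against untreated and 24 at neither, among them Bdnf, Fgf9, Fgf10, Pgf, Angpt1, Il6 and Ccn2. Igf1, which encodes an insulin-like growth factor, rose by 1.10 ± 0.09 at 1 uM (log2 fold change ± SE, n = 3; limma adjusted p = 8.65e-06), and its binding proteins Igfbp2 and Igfbp3 rose by 0.86 (adjusted p = 0.000192) and 1.09 (adjusted p = 0.00126). Gas6, a ligand of the TAM receptors, rose by 1.00 (adjusted p = 0.000651) at 1 uM and 0.89 (adjusted p = 0.00328) at 10 uM. Vegfd, a lymphatic growth factor, rose by 0.77 (adjusted p = 0.000157) and 0.80 (adjusted p = 0.000234), while Vegfc rose by 0.72 (adjusted p = 0.000143) at 1 uM and was lower by -0.63 at 10 uM than at 1 uM (adjusted p = 0.00476). Fst, the activin antagonist follistatin, rose by 0.86 (adjusted p = 9.29e-05) and 0.59 (adjusted p = 0.0038). Bmp6, which fell with PDGF-AB, rose by 0.68 (adjusted p = 0.000216) at 1 uM and 0.47 (adjusted p = 0.00657) at 10 uM, and Gdf6, of the same superfamily, fell by 0.70 (adjusted p = 0.0073) with PDGF-AB.

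Among the semaphorins, which guide axons and vessels, Sema3d rose by 1.11 (adjusted p = 5.21e-06) at 1 uM and 0.67 (adjusted p = 0.000825) at 10 uM. Sema3a fell by 1.31 (adjusted p = 4.61e-05) and 0.73 (adjusted p = 0.00897), and Sema3e by 0.74 (adjusted p = 0.0014) and 0.67 (adjusted p = 0.00544). Hmga2, a chromatin protein of proliferating mesenchymal cells, fell by 1.39 (adjusted p = 3.84e-05) at 1 uM and 1.00 (adjusted p = 0.00131) at 10 uM. With PDGF-AB, the growth factors Fgf2, Fgf7 and Kitl were higher than with AG1296 10 uM by 0.77 (adjusted p = 0.000292), 0.73 (adjusted p = 0.00323) and 0.54 (adjusted p = 0.00392), and Aspn, a small proteoglycan, was lower by -1.43 (adjusted p = 0.000232). The calls with values here were picked because they held in all 12 fits that left out 1 array. Of all 65 calls of the 45 genes over the 5 comparisons, 19 were lost without at least 1 array. Among these were Igf1 at 10 uM and between the doses, Igfbp2 between the doses, Fgf2 at 10 uM and Sema3e between PDGF-AB and AG1296 10 uM, with adjusted p of up to 0.167. Other settings were not run for these genes in this part.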
